A study of Homo sapiens with 14 samples.

How the data were processed

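Gene expression was measured by sequencing polyA-selected RNA from cultures of SH-EP, an established human neuroblastoma cell line that grows attached to the dish. The labels give a SPARK-ON n-Myc line and an n-Myc control line without SPARK-ON, each with lenalidomide or with its solvent, DMSO. No dose or time of treatment could be read from the labels. The values are raw counts per gene deposited by the authors, in whole numbers and without normalization. Per the labels, the authors' processing notes name FastQC, fastp, HTSeq and edgeR, and the hg38 genome. Versions, the aligner, the strand setting and the annotation release were not given in the sources used here.

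The table held 61533 genes. Its columns were matched to samples by the labels, and 11 columns in 4 groups were used. The other 3 columns could not be matched to labelled samples and were not used. The fit had been planned over 14 libraries in 5 groups, so the planned comparisons with baseline SH-EP cells, and the overlap with them, were not made. The choices of test, gene lists, naming rule and alternatives were made before the data were examined, except those named as chosen later.

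Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with its minimum count of 10, which left 16056 genes. Libraries were scaled by TMM, and expression levels are CPM, counts relative to the TMM-scaled library size by edgeR's cpm function. A one-way layout of the 4 groups, with 7 residual degrees of freedom, was fitted by glmQLFit. Contrasts were tested two-sided by glmQLFTest, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. The common biological coefficient of variation was 9.4%. Fold changes are log2, lenalidomide over DMSO or SPARK-ON over control. Standard errors (SE) are the log2 change divided by the root of the F statistic, and SD is over the libraries of a group. Fitting only the groups compared gave a very different count for lenalidomide in SPARK-ON cells, and its values stand beside the reported ones.

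Gene lists, 26 in number, were written from general knowledge of MYC biology, neuroblastoma cell states, lenalidomide and RNA quality. Each had at least 3 tested members. They were tested with camera at a preset correlation between genes of 0.01, with camera at an estimated correlation, and with fry, with adjustment over the lists within a comparison. Members were also adjusted over the list alone. Camera compares a list with all other genes, whereas fry tests only the list's own members.

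Named genes follow a rule. It takes the genes with the largest positive and negative changes among those that passed, had a mean of at least 5 CPM and did not overlap between groups, then the members of each list with the smallest p, and always MYCN, MYC, MAX and CRBN. The text names part of what the rule gives, picked after the values had been computed. ABCC3, PLK2, FBXO32 and RBKS, and the genes of the model with 1 lenalidomide effect over both lines, fall outside it and were chosen after their values were seen. Gene identifiers were matched to a table of gene names, which covered 61415 of them and 56987 with the same version. Positions are on GRCh38 from GENCODE 29, matched without the version, since only 35940 identifiers were the same with it.

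Simulated counts for 16056 genes in the same layout, with 50 genes changed at each size, were used to test the procedure. For lenalidomide in SPARK-ON cells, 50% of changes of 0.5 on the log2 scale were recovered, and 92% of changes of 3. For the difference between lines in the response, the shares were 18% and 80%. False calls were 6 of 149 and 5 of 124. The simulation gave a gene the same spread in all libraries. In the data the coefficient of variation was 4.71% over the 6 SPARK-ON libraries and 12.9% over the 5 control libraries. These shares and false calls therefore do not cover a spread that differs between lines.

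Alternatives were other scalings (RLE, library size alone), other filters, DESeq2 1.42.0, limma-voom 3.58.1, only the groups compared, a replicate block, stricter thresholds and omission of each library. DESeq2 was given all genes with any read and used its own filter, so tool and genes tested changed together wherever its counts stand beside those of edgeR. Thinning to the smallest library, a robust fit, list tests without each library and in the fit of the groups compared, the alternatives of the fit of the 6 SPARK-ON libraries, and an additive model were added after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Replicates carry numbers only. The labels do not say whether they are separate cultures, so p-values measure only the spread between these samples.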

Results

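RNA counts were compared across 11 libraries of SH-EP cells. SPARK-ON, per the series design, brings n-Myc to phase separate when lenalidomide is added, without a change in its concentration. There were 3 SPARK-ON libraries in DMSO, 3 SPARK-ON libraries with lenalidomide, 3 control libraries in DMSO and 2 control libraries with lenalidomide. Total counts were 16174321, 14647340 and 19244198 for SPARK-ON in DMSO, and 15980539, 15769113 and 6614671 for SPARK-ON with lenalidomide. They were 19526965, 17212452 and 21511684 for control cells in DMSO, and 16310438 and 19748302 for control cells with lenalidomide. At these depths a count of 0 allowed between 0.143 and 0.441 CPM per library (3 reads), and all floors and counting intervals cover counting error only. Mitochondrially encoded transcripts took between 2.27% and 2.84% of counts.

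The lines separated on the first principal component, with 70.1% of the variance. SPARK-ON lenalidomide replicate 3, the library with the fewest counts, stood apart on the second component (5.16% of the variance) at -50.6, against -4.7 to 13.7 for the others. Control DMSO replicate 1 stood apart on the third component (4.69% of the variance) at 38.9, against -20.8 to 16.6 for the others. Control lenalidomide replicate 2 was next at 16.6. Control lenalidomide replicate 1 and control DMSO replicates 2 and 3 lay at -20.8, -19.9 and -15.1. Across genes, control DMSO replicate 1 correlated at r = 0.9874 with control lenalidomide replicate 2, and at 0.984 with control DMSO replicates 2 and 3. Within the control line this axis cut across treatment, and its source was not tested. Pairs of libraries of 1 group correlated at r = 0.9815 to 0.989 across genes, and pairs of 1 line under different treatments at 0.9799 to 0.9881. Pairs from different lines correlated at 0.9272 to 0.9425. Genes are not independent replicates.

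Reads counted as MYCN (ENSG00000134323.12, reference position chromosome 2, 15940564 to 15947007) were abundant in both lines. Both are n-Myc lines per the labels, and these counts cannot tell transcripts of that locus from those of an introduced MYCN. Baseline SH-EP cells were not compared. The MYCN level in SPARK-ON cells was 2277 ± 109 CPM in DMSO and 2508 ± 101 CPM with lenalidomide (SD, n = 3 each). In control cells it was 2426 ± 292 CPM in DMSO (SD, n = 3) and 2546 ± 305 CPM with lenalidomide (SD, n = 2). The MYCN change with lenalidomide was 0.14 (SE 0.082, adjusted p = 0.969) in SPARK-ON cells and 0.07 (SE 0.092, adjusted p = 1) in control cells. In a fit of the 6 SPARK-ON libraries alone, the same MYCN change of 0.14 had SE 0.036 and adjusted p = 0.0233. MYC, a relative of MYCN, had a change of 0.44 in SPARK-ON cells and -0.17 in control cells, and MAX, the partner of both proteins, -0.09 and 0.07, with no call. CRBN, the cereblon gene whose protein binds lenalidomide, had changes of 0.07 and -0.03, also without a call.

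Lenalidomide in SPARK-ON cells is, per the series design, the treatment that makes n-Myc phase separate, and the comparison also holds the compound's own effect. It raised 11 genes. L1CAM, a neural cell adhesion molecule (ENSG00000198910.14, chromosome X, 153861514 to 153886174), rose from 15.4 ± 1.9 to 29.6 ± 0.64 CPM. DIO2, a deiodinase that activates thyroid hormone (ENSG00000211448.14, chromosome 14, 80197527 to 80387757), rose from 85 ± 3.9 to 135 ± 6 CPM. The carboxypeptidase gene CPA4 rose from 44.7 ± 2.7 to 71.3 ± 6.4 CPM and the complement gene C3 from 51.3 ± 3.6 to 80.7 ± 3 CPM (SD, n = 3 each). All 11 genes were higher in each of the 3 lenalidomide libraries than in any DMSO library of the line. Chance separates such groups, either way, for 10% of unselected genes. These 11 were called from the same libraries, so their separation follows largely from the call and is no further evidence.

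In the same comparison L1CAM changed by 0.94 (SE 0.13, adjusted p = 0.00727), DIO2 by 0.67 (SE 0.087, adjusted p = 0.00727), CPA4 by 0.68 (SE 0.099, adjusted p = 0.0118) and C3 by 0.66 (SE 0.098, adjusted p = 0.0133). In control cells, without SPARK-ON, lenalidomide changed L1CAM by 1.4 (SE 0.25), CPA4 by 0.82 (SE 0.16) and C3 by 0.92 (SE 0.43), more than in SPARK-ON cells. DIO2 changed less there, by 0.46 (SE 0.1), and none of these was called in control cells. KCNJ2, a potassium channel gene, rose by 0.87 (adjusted p = 0.029) and ANXA8, an annexin gene, by 0.80 (adjusted p = 0.0162). ANXA8 has close paralogs, and how reads shared with them were counted is not given in the sources used here. DKK1, a secreted Wnt inhibitor, rose by 0.54 (adjusted p = 0.0414) and PLAU, the urokinase gene, by 0.51 (adjusted p = 0.0162). ABCC3, an efflux transporter gene, rose by 0.50 (adjusted p = 0.0162), PLK2, a polo-like kinase gene, by 0.42 (adjusted p = 0.0374) and FBXO32, a ubiquitin ligase subunit gene, by 0.42 (adjusted p = 0.0263).

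No gene passed as lower: edgeR called 11 genes higher and 0 lower of 16056, with 860 genes at an unadjusted p below 0.05. DESeq2, given 33507 genes without that expression filter, called 42 higher and 2 lower, where edgeR without the filter called 31 and 4. On the 16056 genes limma-voom called 14 and 0. Fitting only the 6 SPARK-ON libraries called 381 of 14652 genes, 263 higher and 118 lower, including all 11. That fit had a coefficient of variation of 4.71%, against 9.4% over all 11 libraries and 12.9% over the 5 control libraries. Its median prior degrees of freedom, the weight of the spread shared across genes, were 67, against 10.6 over all 11 libraries. The p-values of single genes in the 6-library fit therefore rest heavily on that shared spread. Of the calls of the 6-library fit 69% were higher. DESeq2 on the same 6 libraries made 259 calls, 53.3% of them higher, where its own filter left 7629 genes. With a replicate block over all libraries the count of 11 became 2, and with a block nested within line 0 (524 genes at an unadjusted p below 0.05). It became 1 without lenalidomide replicate 1 and 0 without lenalidomide replicate 2 (628 genes at an unadjusted p below 0.05). It became 5 without lenalidomide replicate 3, and 0 without DMSO replicate 1, 2 or 3 (614, 666 and 607 genes at an unadjusted p below 0.05). In the 6-library fit the count of 381 became 163, 209 and 348 without lenalidomide replicates 1, 2 and 3, and 181, 269 and 242 without DMSO replicates 1, 2 and 3.

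**Figure D1:**
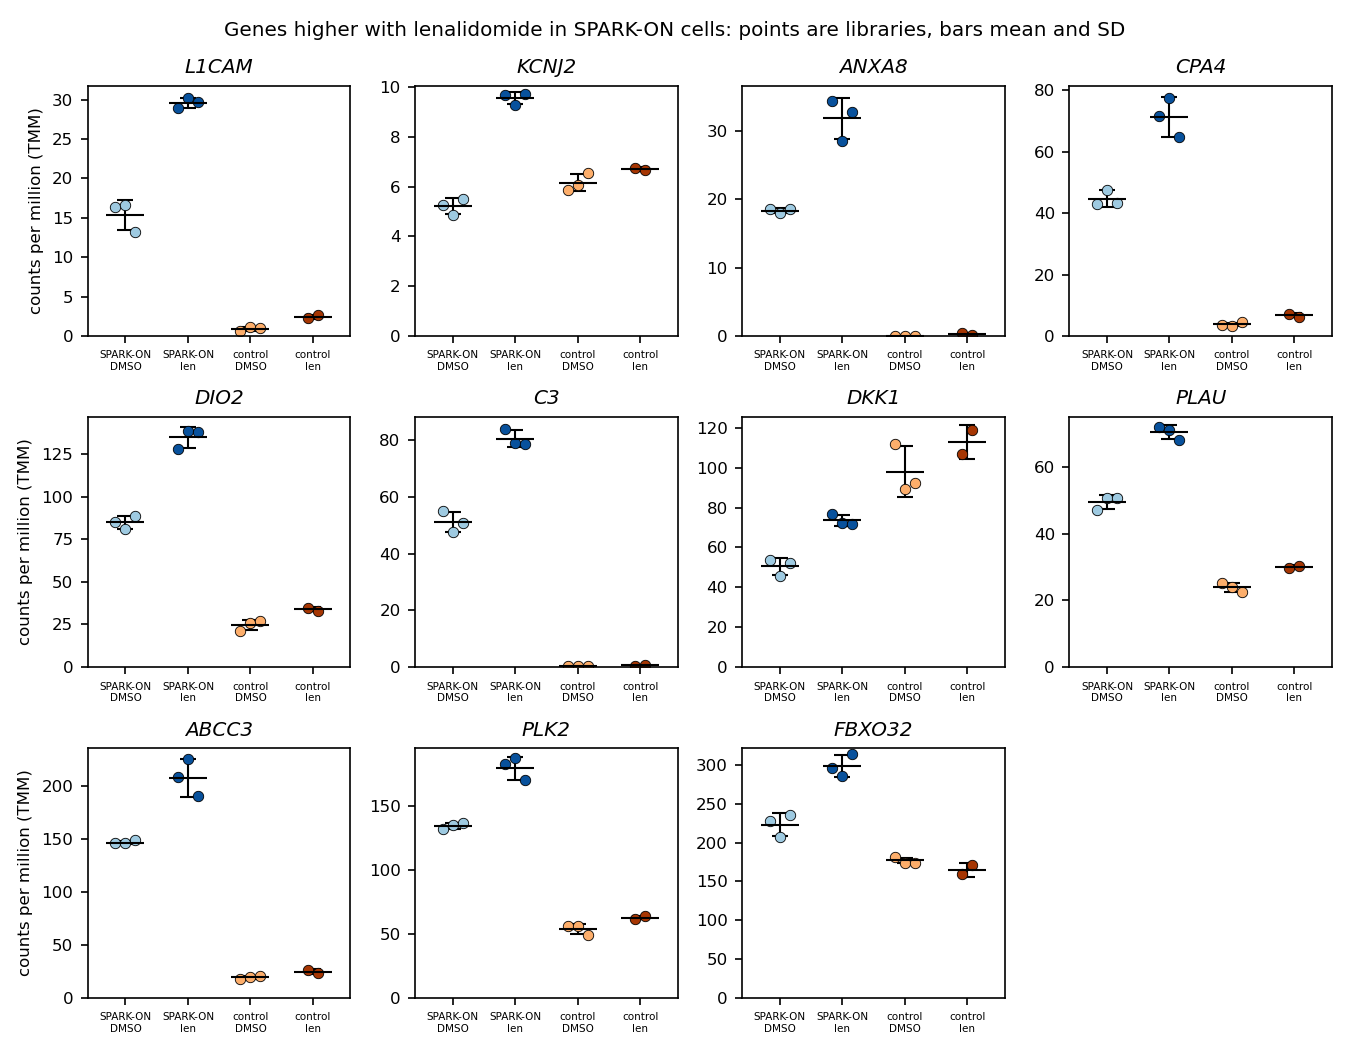
Expression in TMM-scaled CPM (vertical axes from 0) of the 11 genes called for lenalidomide in SPARK-ON cells, by line and treatment. Points are libraries (n = 3, 3, 3 and 2), long bars are means and whiskers SD, and in each panel the 3 SPARK-ON lenalidomide libraries lie above the 3 SPARK-ON DMSO libraries.

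Genes of growth arrest, of TGF-beta and YAP responses and of NF-kappaB and cytokines lay higher with lenalidomide in SPARK-ON cells than other genes did. Of 22 growth arrest genes 19 had a positive change (median 0.12), 1 rose (DKK1), 0 fell, and 4 rose when adjusted over the list alone. CDKN1A, the gene of the cyclin-dependent kinase inhibitor p21 (chromosome 6, 36676460 to 36687339), went from 37.2 ± 3 to 50.5 ± 2.2 CPM (SD, n = 3 each), a change of 0.44 with adjusted p = 0.161. In the 6-library fit CDKN1A had adjusted p = 2.98e-05, and 5 of 21 growth arrest genes rose. Of 22 TGF-beta and YAP genes 20 had a positive change (median 0.22), 0 rose or fell over all genes with 8 at an unadjusted p below 0.05, 5 rose when adjusted over the list alone, and 7 of 22 rose in the 6-library fit. TGFBI, a matrix protein gene named for its response to TGF-beta, had a change of 0.23 (adjusted p = 0.269, and 2.68e-05 in the 6-library fit). Of 17 NF-kappaB and cytokine genes 15 had a positive change (median 0.27), 0 rose or fell over all genes with 4 at an unadjusted p below 0.05, 3 rose when adjusted over the list alone, and 4 of 16 rose in the 6-library fit. NFKB2, an NF-kappaB subunit gene, had a change of 0.33 (adjusted p = 0.2, and 3.15e-05 in the 6-library fit) and TNFAIP3, an inhibitor of the pathway, of 0.51 (0.00367 in the 6-library fit). Camera gave adjusted p = 5.41e-06, 1.7e-07 and 4.4e-07 for the 3 lists in this order, and adjusted p = 0.00938 for each with an estimated correlation.

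Ribosome biogenesis and heat shock genes lay lower with lenalidomide in SPARK-ON cells. Of 34 ribosome biogenesis genes, needed to make ribosomal RNA and assemble ribosomes, 3 had a positive change (median -0.14), 0 rose or fell over all genes or adjusted over the list alone, and 8 were lower at an unadjusted p below 0.05. In the 6-library fit 10 of these 34 fell and 0 rose, among them LYAR at -0.34 (adjusted p = 3.46e-05), DKC1 at -0.22 (adjusted p = 0.000205) and NOLC1 at -0.21 (adjusted p = 0.000465). Of 14 heat shock and chaperone genes 0 had a positive change (median -0.099), 0 rose or fell over all genes or adjusted over the list alone, and 3 were lower at an unadjusted p below 0.05. In the 6-library fit 3 of 13 fell, among them HSPD1, a mitochondrial chaperone gene, at -0.18 (adjusted p = 0.000743), and HSP90AB1 at -0.15 (adjusted p = 0.00462). Camera gave adjusted p = 2.56e-11 for ribosome biogenesis and 7.63e-05 for heat shock, and adjusted p = 0.0265 and 0.0176 with an estimated correlation.

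Another 8 lists passed camera for lenalidomide in SPARK-ON cells with the preset correlation alone. Of 29 extracellular matrix and adhesion genes 26 had a positive change (median 0.16), 3 rose when adjusted over the list alone, and adjusted p = 1.14e-08 became adjusted p = 0.131 with an estimated correlation. In the 6-library fit 8 of 28 rose, among them THBS1 by 0.42 (adjusted p = 1.5e-11) and TIMP3 by 0.64 (adjusted p = 0.000521), and this list had adjusted p = 0.0197 with an estimated correlation there. Of 28 nucleotide, one-carbon and polyamine synthesis genes 2 had a positive change (median -0.12), and adjusted p = 1.84e-07 became adjusted p = 0.0754 with an estimated correlation. In the 6-library fit 7 of 28 fell, among them PSAT1, of serine synthesis, at -0.20 (adjusted p = 0.00152) and ODC1, of polyamine synthesis, at -0.16 (adjusted p = 0.00627). Translation factors and aminoacyl-tRNA synthetases (median -0.06), cell cycle and DNA replication (median -0.03) and cytosolic ribosomal proteins (median -0.042) lay lower, with adjusted p = 0.00111, 0.0172 and 0.0319. With an estimated correlation these had adjusted p = 0.254, 0.131 and 0.785. Interferon-stimulated genes (median 0.12), mesenchymal neuroblastoma identity (median 0.07) and mitochondrially encoded transcripts (median 0.098) lay higher, with adjusted p = 0.0123, 0.0103 and 0.0152. With an estimated correlation these had adjusted p = 0.0668, 0.36 and 0.43. Over all genes no member of these 8 lists rose or fell by edgeR, with 10 extracellular matrix genes higher and 5 nucleotide synthesis genes lower at an unadjusted p below 0.05. Without SPARK-ON lenalidomide replicate 3, cytosolic ribosomal proteins had adjusted p = 0.135, cell cycle 0.052, mesenchymal identity 0.052, interferon-stimulated genes 0.0513 and mitochondrial transcripts 0.226, and 8 lists passed. The call of cytosolic ribosomal proteins was also lost without lenalidomide replicate 1 (adjusted p = 0.0864) or DMSO replicate 3 (0.366), and that of cell cycle without lenalidomide replicate 2 (0.0546) or DMSO replicate 3 (0.0559). Interferon-stimulated genes lost theirs without DMSO replicate 1 (0.0625), and mitochondrial transcripts without DMSO replicate 2 (0.136).

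The remaining 13 lists did not pass camera in the fit of all libraries. Antigen presentation had adjusted p = 0.0506, and 0.0294 in the 6-library fit (adjusted p = 0.203 with an estimated correlation there), p53 targets 0.234, the hypoxia response 0.234, markers of other cell types 0.331, cholesterol and fatty acid synthesis 0.343 and glycolysis and glutamine use 0.358. For lenalidomide in SPARK-ON cells, antigen presentation passed under library size scaling (adjusted p = 0.0466), and without DMSO replicate 3 it and p53 targets passed (adjusted p = 0.0437 each), all at the preset correlation. With an estimated correlation and all libraries they had adjusted p = 0.131 and 0.566. Immediate early genes had 0.442, the integrated stress and unfolded protein responses 0.487, and the MYC and MAX network 0.687. Adrenergic neuroblastoma identity, apoptosis regulators and cereblon ligase with lenalidomide substrates had 0.874 each. Replication-dependent histones had 0.687, with a median of 0.28, a mean of -0.19 and a test directed lower. Median, mean and test also differed in sign for the adrenergic, apoptosis and cereblon lists. Adjusted over the list alone, 3 hypoxia genes were higher and 1 lower, 2 histone genes were lower, and 1 gene each of p53 targets and of the cereblon list was higher. The directional test of fry, which does not compare a list with other genes, passed for 9 of the 26 lists. These were the 5 that passed camera with both correlations, nucleotide synthesis (adjusted p = 0.0241), interferon-stimulated genes (0.0241), antigen presentation (0.0109) and the hypoxia response (0.0241). The mixed test of fry, which counts changes either way, passed for 10 lists, among them hypoxia (adjusted p = 0.000109), the cereblon list (0.00106) and histones (0.0178).

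**Figure D2:**
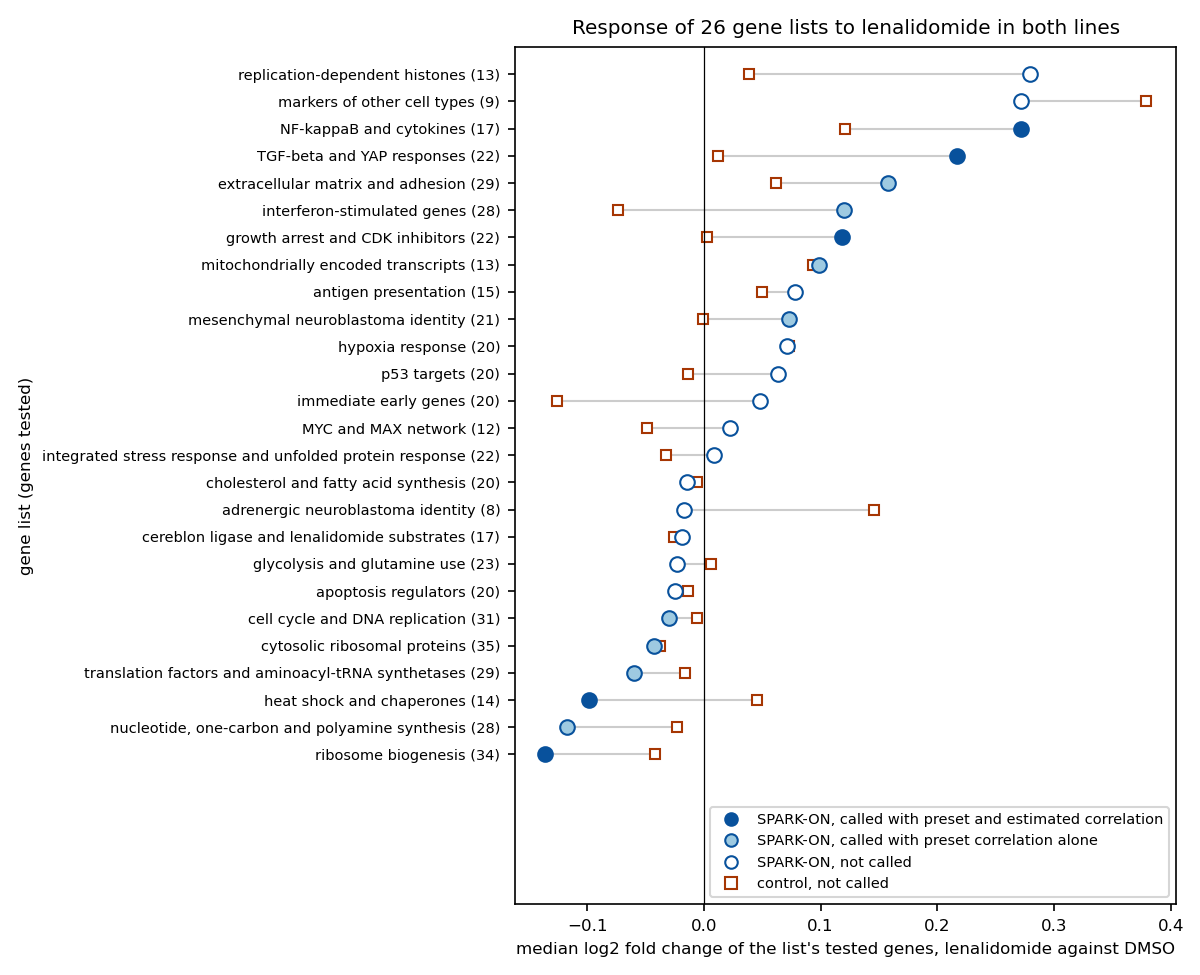
Median log2 change with lenalidomide (horizontal axis) of the tested genes of each of 26 lists (vertical axis, number of genes in brackets), in SPARK-ON (circles) and control cells (squares). Dark circles passed camera with preset and estimated correlation, pale circles with the preset one alone, and no list passed in control cells.

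Lenalidomide in control cells gives the effect of the compound without SPARK-ON. In the fit of all 11 libraries it raised 6 genes and lowered 1. The SE and p-values of that fit use a spread estimated over both lines. Its coefficient of variation was 9.4%, against 12.9% over the 5 control libraries and 4.71% over the 6 SPARK-ON libraries. These p-values therefore do not measure the spread of control cells alone, and the same holds for the difference in response between lines. POSTN, the gene of the matrix protein periostin (chromosome 13, 37562583 to 37598844), rose from 1.26 ± 0.68 (n = 3) to 8.22 ± 0.63 CPM (n = 2), by 2.73 on the log2 scale (SE 0.38, adjusted p = 0.0118). GNAZ, a G protein subunit gene (chromosome 22, 23070361 to 23125037), fell from 11.9 ± 1 to 4.14 ± 0.76 CPM, a change of -1.51 (SE 0.21, adjusted p = 0.0118). SEMA6B, a semaphorin gene, rose from 198 ± 7.4 to 301 ± 25 CPM, by 0.61 (adjusted p = 0.0255).

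Control cells also had higher LYPD6 (0.78, adjusted p = 0.0409), ZNF692 (0.63, adjusted p = 0.0409), RHOB, a small GTPase gene (0.54, adjusted p = 0.0469), and RBKS, the ribokinase gene (1.82, adjusted p = 0.0409). Of 29 extracellular matrix genes 1 rose (POSTN), and of 17 genes of the cereblon list 1 rose (ZNF692), with the same counts adjusted over the list alone. By camera 0 of 26 lists passed, with either correlation and by fry's directional test, and 5 had an unadjusted p below 0.05 at the preset correlation. The mixed test of fry passed for 3 lists, all of which also passed it in SPARK-ON cells: the cereblon list (adjusted p = 4.21e-05), NF-kappaB (adjusted p = 0.00408) and hypoxia (adjusted p = 0.00408). Omission of lenalidomide replicate 1 or 2 let 1 and 4 lists pass camera, and omission of DMSO replicate 1, 2 or 3 let 1, 2 and 4 pass. In each case cytosolic ribosomal proteins were among them, higher without lenalidomide replicate 1 or DMSO replicate 1 and lower without the others. These calls used the preset correlation, and with all libraries this list had adjusted p = 0.932 with an estimated correlation. The count of 7 genes (774 of 16056 at an unadjusted p below 0.05) became 0 in a fit of the 5 control libraries alone (295 of 14666 by edgeR), where limma-voom called 0 and DESeq2 3. It became 0 without lenalidomide replicate 1 or 2 (837 and 1445 genes at an unadjusted p below 0.05), where the lone sample left is assumed to vary like the other groups. It became 21 without DMSO replicate 1, and 2 without DMSO replicate 2 or 3.

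The difference in lenalidomide response between lines is the test of whether SPARK-ON cells responded otherwise than control cells. Growth arrest genes lay higher in that difference and heat shock genes lower. Of 22 growth arrest genes 19 had a positive difference (median 0.19), and 1 was higher adjusted over the list alone. The list's mean change was 0.18 in SPARK-ON and -0.34 in control cells, and its median 0.12 and 0.0027. In control cells 1 member was lower adjusted over the list alone, so the difference also holds falls there. CDKN1A had a change of 0.44 in SPARK-ON cells and -0.24 in control cells (34 ± 2.6 CPM in DMSO, n = 3, and 28.7 ± 3.9 CPM with lenalidomide, n = 2). Of 14 heat shock genes 1 had a positive difference (median -0.18), and 2 were lower adjusted over the list alone. The list's median was -0.099 in SPARK-ON and 0.046 in control cells, where 1 member was higher adjusted over the list alone. The difference in response holds the same DMSO libraries, with opposite sign, as the comparison of lines before lenalidomide. In that comparison growth arrest had a median of -0.27 and a mean of 0.198, and heat shock a median of 0.247. Both results are therefore not independent, and how much the DMSO libraries add to the difference in response was not tested. HSPD1 had a difference of -0.26, from 2000 ± 40 to 1770 ± 32 CPM in SPARK-ON cells (n = 3 each) and from 1660 ± 32 (n = 3) to 1770 ± 38 CPM (n = 2) in control cells.

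Camera gave adjusted p = 8.86e-05 for each of the 2 lists, and adjusted p = 0.026 for each with an estimated correlation. No single gene passed: edgeR called 0 of 16056, with 669 at an unadjusted p below 0.05 where chance gives 803, limma-voom called 0 and DESeq2 3. The difference of CDKN1A was 0.68 (SE 0.149, adjusted p = 0.725). The smallest adjusted p was 0.471, for GNAZ, with a difference of 1.58 (95% interval 0.984 to 2.18). For genes raised in SPARK-ON cells the 95% interval of the difference was -1.05 to 0.138 for L1CAM, -0.533 to 0.246 for CPA4 and -0.0756 to 0.495 for DIO2. It excluded 0 for 4 of the 11, each without a call: 0.284 to 1.2 for KCNJ2, 0.296 to 0.742 for FBXO32, 0.0407 to 0.638 for DKK1 and, the other way, -4.52 to -0.699 for ANXA8 (adjusted p = 1, 0.725, 1 and 1). The 11 were picked by their rise in SPARK-ON cells, which is part of this difference. Their differences therefore tend to be too high, and the intervals do not allow for that. ANXA8 lay near 0 in control cells, at 0.0159 ± 0.028 CPM in DMSO (n = 3) and 0.269 ± 0.16 CPM with lenalidomide (n = 2), so its interval depends on few reads. TGF-beta and YAP responses passed with the preset correlation (adjusted p = 0.0029, and adjusted p = 0.0667 with an estimated correlation), but not without control DMSO replicate 2 (adjusted p = 0.0502). NF-kappaB and cytokines, with a median difference of 0.24, did not pass camera (adjusted p = 0.0925, and adjusted p = 0.282 with an estimated correlation). In control cells that list had a median change of 0.12.

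SPARK-ON cells in DMSO were compared with control cells in DMSO for the difference between lines before lenalidomide. Genes of antigen presentation and NF-kappaB were higher in SPARK-ON cells, and genes of the hypoxia response were lower. NLRP1, an inflammasome sensor gene (ENSG00000091592.16, chromosome 17, 5499427 to 5619424), had 250 ± 11 CPM in SPARK-ON and 0.159 ± 0.14 CPM in control cells (SD, n = 3 each), a TMM-scaled ratio of 1550 from 12774 and 9 summed reads (95% counting interval 817 to 3390). IGFBP5, which binds insulin-like growth factors (chromosome 2, 216672105 to 216695525), had 1.66 ± 0.41 CPM in SPARK-ON and 159 ± 25 CPM in control cells, a TMM-scaled ratio of 96.9 toward control cells from 84 and 8901 summed reads (95% counting interval 78.2 to 122).

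Of 16056 genes 6675 (41.6%) differed between lines by edgeR, 3395 higher and 3280 lower in SPARK-ON cells. With library size scaling alone 4262 were higher and 2547 lower, and the median log2 change over all genes was 0.102, against 0.0114 with TMM. A change of at least 1 on the log2 scale was seen for 2396 genes, 1574 higher and 822 lower. CCDC172, ACTR3C, GALNT18 and LINC01234 had 0 reads in control DMSO libraries and were at least 342-fold, 281-fold, 265-fold and 219-fold higher in SPARK-ON cells, from a floor of 3 reads over the group and TMM-scaled library sizes. C5orf46 and DSG2, a desmosomal cadherin gene, had 0 reads in SPARK-ON DMSO libraries and were at least 400-fold and 295-fold higher in control cells. PCK1, of gluconeogenesis, and ZPLD1 had 3 reads in the lower line, with TMM-scaled ratios of 549 (188 to 2660) and 259 (88.3 to 1260). MYCN did not pass (-0.09, SE 0.082, adjusted p = 0.404), and CRBN was lower in SPARK-ON cells, with a change of -0.56 (SE 0.07, adjusted p = 3.72e-06), at 257 ± 14 against 378 ± 15 CPM (SD, n = 3 each).

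Of 15 antigen presentation genes 13 were higher and 0 lower in SPARK-ON cells (median 0.86), with 13 higher adjusted over the list alone. B2M, the light chain of class I molecules, was higher by 0.83, NLRC5, their transcriptional activator, by 1.07 and HLA-B by 5.20, although HLA-B is polymorphic and has paralogs, so its reads are less certain. Of 17 NF-kappaB and cytokine genes 12 were higher and 1 lower (median 1.67), with 13 and 1 adjusted over the list alone, and NFKB2 was higher by 2.01, ICAM1 by 2.74 and the inhibitor gene NFKBIA by 1.51. Camera gave adjusted p = 6.52e-08 and 2.07e-06, and adjusted p = 0.00554 and 0.00733 with an estimated correlation. Of 28 interferon-stimulated genes 14 were higher and 2 lower, with 15 and 2 adjusted over the list alone, among them OAS2 by 4.23, BST2 by 2.17 and IFIT3 by 1.25. This list had adjusted p = 0.0326, and adjusted p = 0.15 with an estimated correlation.

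Of 20 hypoxia response genes 16 were lower and 2 higher in SPARK-ON cells (median -0.84), with 17 and 2 adjusted over the list alone. VEGFA, an angiogenic factor gene, changed by -1.66, NDRG1 by -1.79, the carbonic anhydrase gene CA9 by -4.55 and the lysyl oxidase gene LOX by -2.52. Camera gave adjusted p = 1.72e-12, and adjusted p = 0.00205 with an estimated correlation. Of 21 genes of mesenchymal neuroblastoma identity 11 were lower and 2 higher (median -0.44), with 12 and 2 adjusted over the list alone, among them SOX9 at -2.84 (SE 0.075), CD44 at -1.25 and VIM at -1.21. That list had adjusted p = 5.21e-06, and adjusted p = 0.15 with an estimated correlation.

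Of 35 cytosolic ribosomal protein genes 29 were lower and 0 higher in SPARK-ON cells (median -0.34), with 31 lower adjusted over the list alone and 20 lower under library size scaling. RPL13A changed by -1.04 and RPS19 by -0.93. Of 20 cholesterol and fatty acid synthesis genes 11 were lower and 0 higher, with 11 adjusted over the list alone, among them SCD at -1.09. Of 20 immediate early genes 11 were lower and 2 higher, with 13 and 3 adjusted over the list alone, among them JUN at -1.87 and JUND at -1.34. Of 22 stress response genes 11 were lower and 3 higher, with 12 and 3 adjusted over the list alone, among them CHAC1 at -1.80. These 4 lists had adjusted p = 9.05e-05, 0.00163, 0.00163 and 0.0203 with the preset correlation. With an estimated correlation they had adjusted p = 0.603, 0.15, 0.188 and 0.549.

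For SPARK-ON DMSO against control DMSO, 3 more lists passed narrowly. Of 23 glycolysis and glutamine genes 13 were lower and 2 higher, with the same counts adjusted over the list alone, among them GPI at -0.92 (list adjusted p = 0.0249, adjusted p = 0.566 with an estimated correlation, 0.0537 under library size scaling). Of 29 extracellular matrix genes 13 were lower and 9 higher, with 13 and 10 adjusted over the list alone, among them COL1A2 at -3.48 (list adjusted p = 0.0485, adjusted p = 0.603 with an estimated correlation, 0.066 under library size scaling). Of 22 growth arrest genes 11 were lower and 4 higher, with 12 and 5 adjusted over the list alone, a median of -0.27 and a mean of 0.20 (list adjusted p = 0.0485, adjusted p = 0.15 with an estimated correlation, 0.0619 under library size scaling). The growth arrest call was lost without SPARK-ON DMSO replicates 1, 2 and 3 (adjusted p = 0.0657, 0.0699 and 0.0557) and without control DMSO replicate 2 (0.0501). The extracellular matrix call was lost without the same SPARK-ON replicates (adjusted p = 0.0524, 0.0537 and 0.0749) and without control DMSO replicates 2 and 3 (0.132 and 0.0588).

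**Figure D3:**
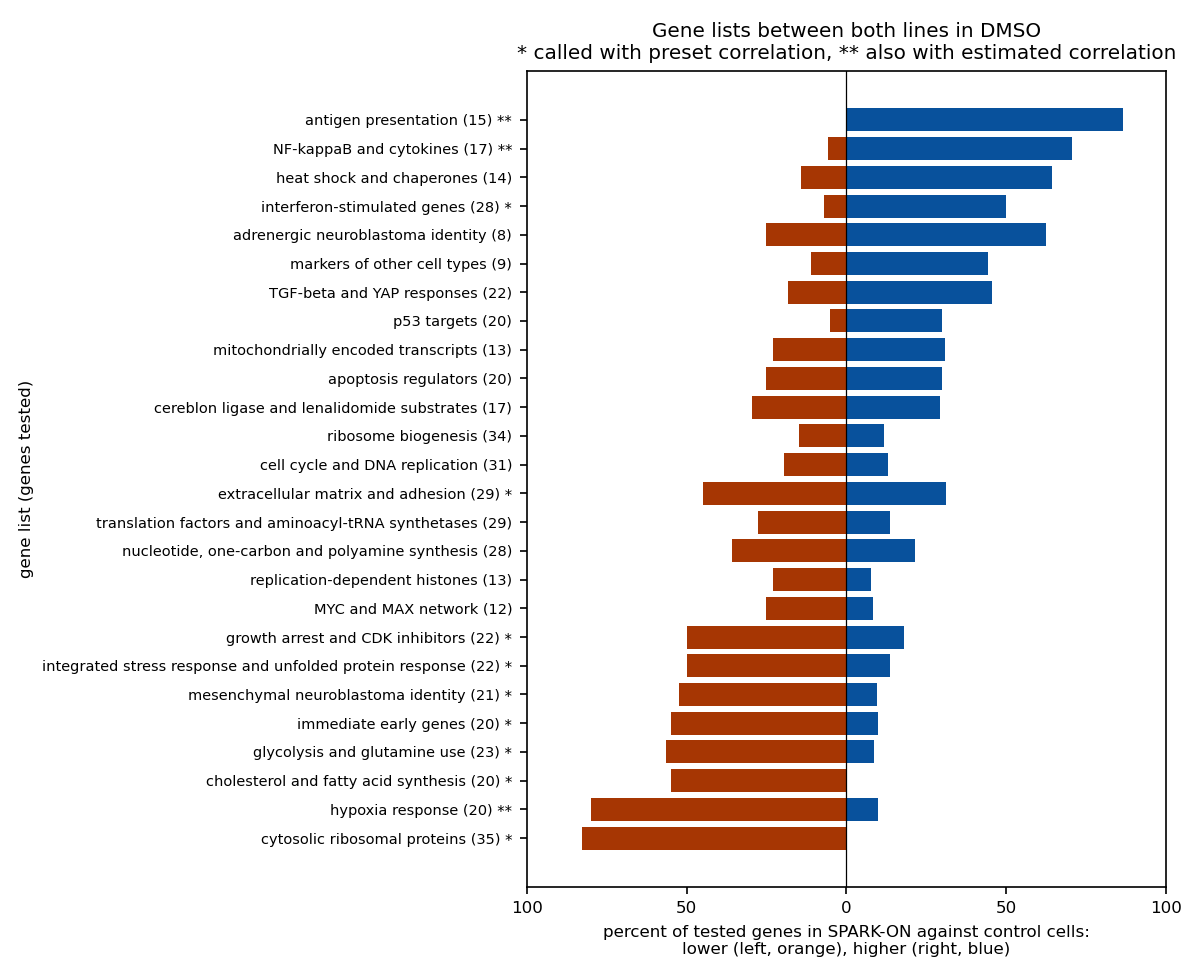
Percent of the tested genes of each list (vertical axis, number of genes in brackets) that were lower (left) or higher (right) in SPARK-ON than in control cells in DMSO, at an adjusted p below 0.05. Antigen presentation reaches furthest to the right with 13 of 15 genes, and lists with 2 asterisks passed camera with preset and estimated correlation.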

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

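The list tests without each library, the comparison of lists between lines as a test for the line that carries SPARK-ON, and the list tests of the 6-library fit were chosen only after the results were seen. The difference in lenalidomide response between lines singled out 7 lists by camera with the preset correlation. Growth arrest had adjusted p = 8.86e-05 and heat shock 8.86e-05, TGF-beta and YAP responses 0.0029, ribosome biogenesis 0.00594, nucleotide, one-carbon and polyamine synthesis 0.00594, extracellular matrix 0.00899 and immediate early genes 0.0271. With an estimated correlation the last 4 had adjusted p = 0.434, 0.434, 0.708 and 0.434, and TGF-beta and YAP responses 0.0667. Growth arrest and heat shock passed at the preset correlation with each library left out in turn. Ribosome biogenesis, nucleotide synthesis and extracellular matrix did not pass without control lenalidomide replicate 2 (0.335, 0.187 and 0.302) or control DMSO replicate 2 (0.0658, 0.0502 and 0.38). TGF-beta and YAP responses did not pass without control DMSO replicate 2 (0.0502), and extracellular matrix without control DMSO replicate 3 (0.0833). Immediate early genes did not pass without SPARK-ON lenalidomide replicate 1 (0.145), SPARK-ON DMSO replicate 2 (0.0804), control lenalidomide replicate 1 (0.744), or control DMSO replicate 1 (0.0799) or 2 (0.0994).

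The shift of 13 lists with lenalidomide in SPARK-ON cells was weighed against technical explanations. Correction for a smooth trend on GC content and transcript length left 13 of 13 lists past the threshold in the same direction, which argues against that trend as the whole cause. Without SPARK-ON lenalidomide replicate 3, which had the fewest counts, 8 of 13 lists passed and all 13 kept their direction, so a contribution of that library to the other 5 stays open. A response of the line that carries SPARK-ON is a candidate explanation for growth arrest and heat shock, the 2 lists that differed between lines with an estimated correlation. That difference also holds opposite changes in control cells. There 3 growth arrest genes were lower and 2 heat shock genes higher at an unadjusted p below 0.05, with 0 the other way in each list. The difference also shares its DMSO libraries, with opposite sign, with the comparison of lines in DMSO. There the medians of both lists lay the other way, and what this adds was not tested. The construct changed together with the line, and both cannot be told apart. Regrouping the 6 SPARK-ON libraries gives 10 splits, too few for a share under 0.05: the real split called 13 lists and the highest other 7, in the 6-library fit 14 and 9, and with an estimated correlation 5 and 0, so 1 of 10 splits gave as many.

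For the 11 genes higher with lenalidomide in SPARK-ON cells, 1 of 10 splits gave as many genes. The highest other split gave 0 genes, and in the 6-library fit the real split gave 381 and the highest other 1. With 10 splits no share under 0.05 can be had.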

How the results depend on the processing

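Counts are given in the order lenalidomide in SPARK-ON cells, in control cells and, where named, the difference between lines, against 11, 7 and 0 genes as reported. Thinning, the robust fit, list tests without each library and the alternatives of the 6-library fit were chosen after seeing the data. RLE and library size scaling gave 11 and 7 genes, limma-voom 14 and 9 and the robust fit 12 and 7. Without an expression filter they were 35, 27 and 1, and with DESeq2, which also ran without that filter, 44, 24 and 3. The stricter filter gave 10 and 1, thinning 9 and 2, and only the groups compared 381 and 0. A replicate block over all libraries gave 2 and 1, and a block nested within line 0 and 0 (524 and 485 genes at an unadjusted p below 0.05). In SPARK-ON cells replicate numbers showed no sign of pairing: deviations of libraries with the same number correlated at -0.00279 to 0.0149. In control cells these correlations were -0.182 and -0.133. With 2 control lenalidomide libraries the deviations mirror each other, so these values are not separate and do not decide on pairing there. The labels do not say whether equal numbers mean libraries made together. An adjusted p below 0.01 gave 2 and 0 genes, and an absolute log2 change of at least 1 gave 0 and 3, and 2396 between lines, as fewer genes meet a stricter threshold. Omission of single libraries gave 0 to 5 and 0 to 21 genes, and 163 to 348 in the 6-library fit. Where construction does not show it, the cause was not tested.

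Between lines the count of 6675 genes was 5576 to 6927 without single libraries. For lists, an estimated correlation called 5 for SPARK-ON cells, 2 for the difference and 3 between lines, and fry 2 for the difference and 22 between lines. The replicate block over all libraries called 1 list for control cells, as higher and at the preset correlation, where an estimated correlation without the block called 0. Omission of single libraries called 8 to 13 lists for SPARK-ON cells, 1 to 4 for control cells and 2 to 11 for the difference. Reversed changes were all of genes without a call. In control cells CRBN was 0.005 with the nested block, 0.027 without lenalidomide replicate 2 and 0.006 without DMSO replicate 3 (-0.09 to 0.027 over omissions). There MYCN was -0.058 without lenalidomide replicate 1 and -0.032 without DMSO replicate 1 (-0.058 to 0.18 over omissions), and MAX -0.103 without lenalidomide replicate 2 (-0.103 to 0.212). In the difference, MYCN was -0.049 (-0.049 to 0.195) and MAX 0.005 (-0.305 to 0.005) without control lenalidomide replicate 2. The alternatives of the comparisons with baseline SH-EP cells were not run, and the planned fit of 11 libraries became the reported one. SPARK-ON lenalidomide replicate 3, with 6614671 counts, limits the depth of its group.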

Other observations

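The additive model and the test of a response shared by both lines were chosen only after the results were seen, as was thinning. A model with 1 lenalidomide effect over both lines called 34 genes, 33 higher and 1 lower. CPA4 rose by 0.72 and DIO2 by 0.59 (adjusted p = 0.000216 each), L1CAM by 1.04 (adjusted p = 0.000216), RHOB by 0.49 (adjusted p = 0.00115) and POSTN by 2.65 (adjusted p = 0.00125). The value of POSTN rests on control cells, since in SPARK-ON cells it had 0.042 ± 0.036 CPM in DMSO and 0.122 ± 0.12 CPM with lenalidomide (n = 3 each; change 1.75, adjusted p = 0.976). DUSP10, a phosphatase gene that acts on stress-activated kinases, rose by 0.59 (adjusted p = 0.00152), SPP1, the osteopontin gene, by 0.40 (adjusted p = 0.00271) and COL11A1, a fibrillar collagen gene, by 0.46 (adjusted p = 0.00461). NFKB2 rose by 0.32 (adjusted p = 0.0196) and TNFAIP2 by 0.28 (adjusted p = 0.0171). ARPIN, an inhibitor of the Arp complex that branches actin, fell by 0.38 (adjusted p = 0.0188).

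Between lines in DMSO, 14 lists did not pass camera, and each held genes called higher and genes called lower. Of 14 heat shock genes 9 were higher and 2 lower in SPARK-ON cells (adjusted p = 0.334), of 8 adrenergic genes 5 and 2 (0.379), of 22 TGF-beta and YAP genes 10 and 4 (0.0683), and of 9 markers of other cell types 4 and 1 (0.28). Of 34 ribosome biogenesis genes 4 were higher and 5 lower (0.7), of 29 translation genes 4 and 8 (0.202), of 28 nucleotide synthesis genes 6 and 10 (0.283), and of 31 cell cycle genes 4 and 6 (0.549). Of 20 p53 targets 6 and 1 did so (0.407), of 20 apoptosis regulators 6 and 5 (0.596), and of 17 genes of the cereblon list 5 and 5 (0.549). Of 12 genes of the MYC and MAX network 1 and 3 did so (0.379), of 13 mitochondrial transcripts 4 and 3 (1), and of 13 histone genes 1 and 3 (0.496).

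Of the 11 genes higher with lenalidomide in SPARK-ON cells 10 had a positive change in control cells, FBXO32 (-0.099) being the exception, with a median of 0.34 in control cells. A response to lenalidomide that both lines share is a candidate explanation. The directional test of edgeR's fry on these genes in control cells gave adjusted p = 1.9e-06. This equals the unadjusted value, since 1 set was tested. That p-value uses the spread of the fit of all 11 libraries, in which the genes were called, not that of control cells alone. It is therefore not an independent replication. Scaling by library size alone gave a median of 0.336, but it moved the median of all genes in control cells only from 0 to -0.0054, so it could not test library composition, which stays open. No gene passed in both lines by edgeR, and at an unadjusted p below 0.05 in both there were 135 genes, 110 with the same sign, where 41.5 would be expected of independent lists. Both p-values of a gene use the same estimate of its spread, so the lists are not independent and 41.5 is not the chance level here. Across all genes, which are not independent replicates, the changes in both lines had r = 0.0502 and rho = 0.0732. Over the 10638 genes with a mean of at least 5 CPM they had r = 0.141 and rho = 0.104. Of the 381 genes called in the 6-library fit 263 had the same sign in control cells, 194 of the 263 higher and 69 of the 118 lower ones.

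Differences between lines in DMSO covered 6675 genes. With every library thinned to the smallest total 5525 genes were called, which argues against depth as the source. Of the 10 splits of the 6 DMSO libraries 1 gave as many genes and the highest other gave 0, too few splits for a share under 0.05. Every other split mixes both lines within a group, so the large difference between lines enters the spread. Their lack of called genes is therefore largely built in and decides nothing. At the preset correlation the real split called 12 lists and the others 5 to 8, and with an estimated correlation 3 and 0. The lines differ by construct per the labels, SPARK-ON cells come from 1 clone per the series design, and how the control line was derived is not given in the sources used here. Whether the differences come from the construct or from other differences between the lines was not tested.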
